A study of Rattus norvegicus with 52 samples.

How the data were processed

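The deposited files hold 1 table of read counts per gene symbol for all 52 libraries, per the file headers. Per the labels' protocols, total RNA was taken with Trizol, libraries were made from 500 ng with the Lexogen QuantSeq 3' mRNA kit, and each library came from the lung of 1 rat. The submitters' processing notes name fastp, STAR, HTSeq and the assembly mRatBN7.2, in no stated order and with no version. The strand setting and the gene annotation are not given in the sources used here. Values were whole numbers throughout and were used as counts, with no further change by the authors stated. Of 34034 symbols, 29433 match the reference gene table of assembly GRCr8, which was used for names alone, and no coordinates are given. For genes with near-identical copies or a gene on the other strand, the files do not show which one the reads came from.

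Counts were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1). TMM factors, filterByExpr by group and a quasi-likelihood fit (glmQLFit, glmQLFTest) with 1 term per group over all 52 libraries left 17796 genes tested and 39 residual degrees of freedom. The 28 comparisons were 12 of a dosed group against Control, 4 of the highest against the lowest dose of a compound, and 12 of compounds at the same dose value. Tests were two-sided with Benjamini-Hochberg adjustment over all genes tested, and a gene was called at adjusted p under 0.05. DESeq2 1.42.0 (Wald test) was run as an alternative with the same filter. SE of a log2 fold change comes from the edgeR fit, and CPM use the TMM library sizes. The replicate numbers in the titles did not pair libraries across groups: the mean correlation of residuals between libraries of the same number was 0.0138, so no block was used in the main test.

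These 32 gene lists were fixed: neutrophil markers, resident alveolar macrophage markers, recruited monocyte and macrophage markers, chemokines and inflammatory cytokines, T cell markers, B and plasma cell markers, NK and cytotoxic markers, mast cell markers, type 2 response genes, alveolar type 2 cell markers, alveolar type 1 cell markers, injury-associated epithelial genes, ciliated cell markers, club cell markers, goblet and mucous genes, basal cell markers, endothelial markers, extracellular matrix and fibroblast genes, cell cycle genes, cholesterol synthesis genes, oxidative stress (Nrf2) genes, unfolded protein and integrated stress genes, interferon-stimulated genes, complement and acute phase genes, MHC class II genes, coagulation and fibrinolysis genes, lysosome and phospholipid handling genes, immediate early genes, circadian clock genes, erythroid genes, cardiac muscle genes and sex-linked genes. Each was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with the correlation estimated per list. Members were also called with adjustment over the list alone. A library's list score is the mean log2 CPM (prior count 2) of the members. The comparisons, tests, lists, alternatives and rule for named genes were chosen before the data were examined. Covariates from list scores, the set of genes that varied together, the overlap at 0.5 and the intervals of single genes were chosen after the data were seen.

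The rule for named genes took, at the highest dose against Control, the 10 largest positive and the 10 largest negative log2 fold changes among called genes with all 4 dosed libraries on the same side of all 4 controls and a mean of at least 5 CPM in 1 group. It took 3 and 3 at lower doses, between doses and between compounds. Names without a symbol, such as those beginning LOC or RGD, were skipped. In each list described, up to 4 members with the smallest adjusted p, and any member needed to say that it did not pass, were added. Genes by this rule that lost their call when 1 library was left out are named in the report in part. The set that varied together held the 363 genes whose residual log2 CPM correlated above 0.7 with the second principal component within groups, over the 36 libraries outside the DDAC and Control groups.

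The tests were run on simulated counts with 200 changed genes. For BKC at 1 against Control, 54% of genes changed 2-fold and 81% of those changed 4-fold were recovered, with 6 false calls. These were 63%, 86% and 2 for DDAC at 0.25 against Control and 46%, 87% and 10 for BKC against ADEB18 at 0.5. Overlap between compounds was set beside 20 simulations of unchanged groups against the same controls. Within-group correlations used 100000 permutations of libraries within groups. Counts of called genes were set against refits of a comparison's 8 libraries over the 35 ways of making 4 and 4. Splits that mix groups called up to 454, so the false calls above may be too few.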

Results

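Lung tissue from Sprague Dawley rats was profiled by 3' mRNA sequencing after 1 instillation into the trachea of a quaternary ammonium compound, a class of cationic surfactant used in disinfectants. The labels name 4 compounds, ABD, ADEB18, BKC and DDAC, and a Control group given distilled water (DW in the labels). ABD and ADEB18 were given at 0.125, 0.25 and 0.5, BKC at 0.25, 0.5 and 1, and DDAC at 0.0625, 0.125 and 0.25, in a unit that the labels do not state. Each of the 13 groups held 4 rats with 1 library each, 52 libraries in all. BKC and DDAC are the usual abbreviations of benzalkonium chloride, which carries a benzyl group, and didecyldimethylammonium chloride, which carries a pair of decyl chains, although the labels do not spell them out. Total counts per library ran from 8026080 to 13852200, and 16932 to 19355 genes had at least 1 count. The series description says that cell count, lactate dehydrogenase and protein in lavage fluid rose over these doses, and those measurements were not used here. Below, a log2 fold change stands with its SE and a level in CPM, counts scaled to library size, with its SD, n = 4 per group. Genes and lists that lost their call when 1 library was left out are described in part and otherwise given as a number. For a list, the numbers over all genes come first, then the number adjusted over the list alone, the adjusted p of the list test and, marked estimated, its adjusted p with an estimated correlation.

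The comparisons of the 12 dosed groups with Control ask which lung transcripts differ after each compound and dose. Of 17796 genes tested, edgeR called 0 to 4 for ABD, 7 for ADEB18 at both 0.125 and 0.25, 829 for ADEB18 at 0.5, 37, 1629 and 1842 for BKC from its lowest to its highest dose, and 412, 263 and 439 for DDAC. Called genes that also changed at least 2-fold numbered 193 for ADEB18 at 0.5, 325 for BKC at 0.5, 457 for BKC at 1 and 159 for DDAC at 0.25.

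**Figure D1:**
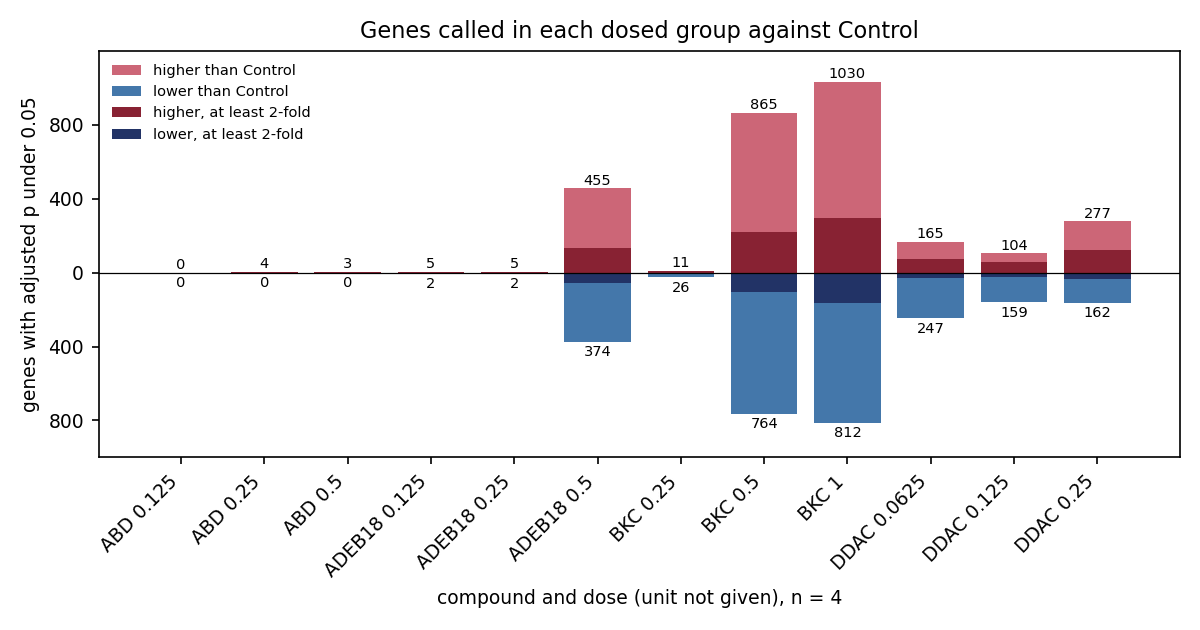
Number of genes with adjusted p under 0.05 in each dosed group against Control (vertical axis, higher above 0 and lower below it), with the darker part for changes of at least 2-fold. BKC at 1 had 1030 genes higher and 812 lower, and ABD at 0.125 had 0 of either by edgeR.

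BKC at 1 raised transcripts of chemokines that attract monocytes. Ccl2 went from 4.38 ± 2.00 CPM in Control to 85.1 ± 19.9 CPM (log2 fold change 4.27 ± 0.56, adjusted p = 5.69e-06), Ccl12 from 1.62 ± 0.867 CPM to 60.6 ± 26.2 CPM (log2 fold change 5.19 ± 0.73, adjusted p = 1.59e-05), and Ccl7 rose by 3.40 ± 0.59. Il24, a cytokine of the interleukin 10 family, rose by 6.45 ± 1.27, and Spp1, which codes for osteopontin, by 6.33 ± 1.21. Saa3, a serum amyloid A, rose by 4.97 ± 0.85, and Lcn2, whose product binds bacterial siderophores, by 4.25 ± 0.90, to 1747 ± 453 CPM. The 10 largest increases also held Kng2 (4.13 ± 0.95), Fam25a (3.48 ± 0.76, 2.28 without BKC 1 replicate 2) and Mmp12 (2.83 ± 0.75), of which Kng2 codes for a kininogen and Mmp12 for the macrophage elastase. The largest decreases included Serpinb10, a serine protease inhibitor (log2 fold change -3.13 ± 0.48, adjusted p = 5.50e-05), Kifc2, a kinesin (-1.74 ± 0.24), Spon2, a matrix protein (-2.14 ± 0.31), Kcnmb2, a potassium channel subunit (-2.41 ± 0.43), S100g, a calcium-binding protein (-2.47 ± 0.63), and Adra2b, an adrenergic receptor (-2.23 ± 0.50). These 16 of the 20 genes named by size kept the call in every leave-one-out fit. In all 1030 genes rose and 812 fell (851 with the 2 groups alone in the fit). The count was 1090 without Control replicate 4 and 1145 and 1144 without BKC 1 replicate 2 or 4 in turn.

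Several of the fixed lists rose with BKC at 1. Of 14 recruited monocyte and macrophage markers, 7 rose, with Arg1 (2.78 ± 0.46) and Lgals3 (1.44 ± 0.28) (9 over the list alone, adjusted p = 1.90e-08, or 0.148 estimated). Of 22 chemokines and inflammatory cytokines, 6 rose and 1 fell (6 up and 1 down over the list alone, adjusted p = 0.000584, or 0.186 estimated). Of 22 cell cycle genes, 8 rose, with Mcm3 (1.01 ± 0.20), Pcna (1.11 ± 0.24) and Cdk1 (1.20 ± 0.29) (17 over the list alone, adjusted p = 2.46e-10, or 0.186 estimated). Among 21 cholesterol synthesis genes, 10 rose, with Cyp51 (1.18 ± 0.20), Fdps (0.87 ± 0.18) and Idi1 (1.27 ± 0.27) (16 over the list alone, adjusted p = 1.24e-09, or 0.144 estimated). Of 13 unfolded protein and integrated stress genes, 4 rose, the chaperone gene Hspa5 by 0.69 ± 0.16 (5 over the list alone, adjusted p = 0.000850, or 0.144 estimated). Of 15 oxidative stress (Nrf2) genes, 3 rose and 1 fell, with the heme oxygenase gene Hmox1 up (5 up and 1 down over the list alone, adjusted p = 0.00614, or 0.186 estimated). Of 13 injury-associated epithelial genes, 5 rose and 1 fell, with the keratin genes Krt8 (0.97 ± 0.22) and Krt18 (0.81 ± 0.18) up (9 up and 1 down over the list alone, adjusted p = 0.00610, or 0.212 estimated). Of 15 lists called, 12 stayed so in every leave-one-out fit.

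Markers of several lung cell types were lower with BKC at 1. Of 10 club cell markers, 6 fell, with Cyp4b1 (-1.05 ± 0.19) (6 over the list alone, adjusted p = 5.11e-07, or 0.144 estimated). Of 11 alveolar type 1 cell markers, 4 fell, with the receptor gene Ager (-0.93 ± 0.20) (5 over the list alone, adjusted p = 0.000811, or 0.286 estimated). Of 15 endothelial markers, 3 fell, with the tight junction gene Cldn5 (-0.65 ± 0.17) (6 over the list alone, adjusted p = 6.81e-05, or 0.286 estimated). Of 9 mast cell markers, 1 fell, the transcription factor gene Gata2 (1 over the list alone, adjusted p = 0.0112, or 0.283 estimated). Tppp3 (-0.92 ± 0.14) was the 1 of 15 ciliated cell markers that fell (adjusted p = 0.0122, or 0.646 estimated). Erythroid genes had 0 of 9 called by edgeR and a median of -0.59 (adjusted p = 0.0273, or 0.621 estimated), and 3 of 19 lysosome and phospholipid handling genes rose, with the cathepsin gene Ctsb at 1.06 ± 0.17 (adjusted p = 0.0150, or 0.186 estimated). The call for ciliated cell markers ended without BKC 1 replicate 2 or 4 or Control replicate 3 (adjusted p up to 0.0698). The call for lysosome and phospholipid handling genes ended without BKC 1 replicate 1 or 2 (adjusted p up to 0.0588). The call for erythroid genes ended without BKC 1 replicate 2 or 3 or Control replicate 2 or 3 (adjusted p up to 0.113). Cldn5 lost its call without Control replicate 2 (adjusted p = 0.0781). Gata2 lost its call without BKC 1 replicate 2 or Control replicate 4 (adjusted p up to 0.0690).

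The other lists did not pass with BKC at 1, given here with the median log2 fold change of their members. Among immune lists these were neutrophil markers (-0.48, adjusted p = 0.481), resident alveolar macrophage markers (0.02, adjusted p = 0.481), T cell markers (0.03, adjusted p = 0.954), B and plasma cell markers (-0.19, adjusted p = 0.481), NK and cytotoxic markers (-0.40, adjusted p = 0.152), type 2 response genes (-0.05, adjusted p = 0.192), interferon-stimulated genes (-0.12, adjusted p = 0.181), complement and acute phase genes (0.15, adjusted p = 0.481) and MHC class II genes (-0.15, adjusted p = 0.359). Among other lists these were alveolar type 2 cell markers (0.23, adjusted p = 0.293), goblet and mucous genes (-0.76, adjusted p = 0.481), basal cell markers (0.11, adjusted p = 0.954), extracellular matrix and fibroblast genes (0.07, adjusted p = 0.481), coagulation and fibrinolysis genes (0.32, adjusted p = 0.262), immediate early genes (0.32, adjusted p = 0.262) and cardiac muscle genes (-0.95, adjusted p = 0.371). Median, mean and direction of the test differed in sign for T cell markers (mean 0.06, tested lower), type 2 response genes (mean 0.50, tested higher) and resident alveolar macrophage markers (mean -0.37, tested lower). The sex-linked list, a check of the labels, had adjusted p = 0.481. Clock genes stand apart below.

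BKC at 0.5 raised 865 genes and lowered 764 (605 in all with the 2 groups alone). Of 13 lists called, 11 stayed so in every leave-one-out fit. Its 3 largest increases were Spp1 (log2 fold change 6.36 ± 1.21, adjusted p = 0.000737), Il24 (5.70 ± 1.25) and Ccl12 (log2 fold change 5.18 ± 0.73, adjusted p = 5.52e-05), and Ccl2 rose by 3.80 ± 0.55. Dlk1, whose product is related to Notch ligands (-3.41 ± 0.87), and Rasl11a, a small GTPase gene (-2.28 ± 0.41), were among its 3 largest decreases. Of 22 cell cycle genes, 17 rose, with Mcm3 (1.16 ± 0.20), Cdk1 (1.62 ± 0.29) and Mki67 (1.58 ± 0.32) (22 over the list alone, adjusted p = 3.09e-18, or 0.189 estimated). Of 14 recruited monocyte and macrophage markers, 6 rose (12 over the list alone, adjusted p = 4.31e-09, or 0.189 estimated). Of 22 chemokines and inflammatory cytokines, 4 rose (4 up and 1 down over the list alone, adjusted p = 0.00392, or 0.275 estimated). Of 21 cholesterol synthesis genes, 7 rose, with Cyp51 (0.86 ± 0.19) (15 over the list alone, adjusted p = 2.48e-07, or 0.189 estimated). Of 13 unfolded protein and integrated stress genes, 2 rose, the chaperone genes Sdf2l1 and Hspa5 (2 over the list alone, adjusted p = 0.0160, or 0.189 estimated). The count was 1062 and 908 without Control replicate 2 or 4 in turn and 467 without BKC 0.5 replicate 3. Sdf2l1 lost its call without BKC 0.5 replicate 3 (adjusted p = 0.0520). Hspa5 did without BKC 0.5 replicate 1, 2 or 3 or Control replicate 1, 2, 3 or 4 (adjusted p up to 0.261).

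Lists of endothelial and epithelial markers tested lower with BKC at 0.5. Of 15 endothelial markers, 6 fell, with Cldn5 (-0.75 ± 0.17) and Cdh5 (-0.61 ± 0.17) (13 over the list alone, adjusted p = 2.55e-09, or 0.189 estimated). Of 11 alveolar type 1 cell markers, 5 fell, with Ager (-0.88 ± 0.20) (6 over the list alone, adjusted p = 0.000234, or 0.278 estimated). Of 10 club cell markers, 3 fell, with Cyp4b1 (-0.96 ± 0.19) (5 over the list alone, adjusted p = 0.000342, or 0.251 estimated). Of 9 mast cell markers, 2 fell, Gata2 and the receptor gene Kit (2 over the list alone, adjusted p = 0.0138, or 0.295 estimated). By edgeR 0 of 9 erythroid genes were called and 5 were lower over the list alone (adjusted p = 0.000391, or 0.301 estimated). Cdh5 lost its call without BKC 0.5 replicate 1 or 3 or Control replicate 2 (adjusted p up to 0.133). Kit lost its call without BKC 0.5 replicate 3 or Control replicate 2 or 4 (adjusted p up to 0.210).

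BKC at 0.25 raised 11 genes and lowered 26, with clock genes first among the increases: Dbp (log2 fold change 2.60 ± 0.39, adjusted p = 0.000456), Nr1d1 (2.07 ± 0.33) and Per3 (1.88 ± 0.30). The transcription factor gene Zbtb16 (-2.51 ± 0.44) was among the 3 largest decreases. Ccl2 stood at 6.48 ± 1.40 CPM and did not pass (log2 fold change 0.56 ± 0.53, adjusted p = 0.778). With the clock score as a covariate 2 genes were called, with the set score described below (5.07 ± 0.366 against 4.50 ± 0.116) 8, of them 6 up and 2 down, and with the 2 groups alone 12. By the list test, cell cycle genes were higher, with 0 of 22 called by edgeR or over the list alone and a median of 0.36 (adjusted p = 0.00351, or 0.975 estimated), and neutrophil markers lower, with 0 of 10 called, 1 over the list alone and a median of -0.64 (adjusted p = 0.00637, or 0.975 estimated). The count was 18 and 7 without Control replicate 2 or 4 in turn and 17, 18, 23 and 7 without BKC 0.25 replicate 1, 2, 3 or 4 in turn. Zbtb16 lost its call without Control replicate 4 (adjusted p = 0.0947).

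From 0.25 to 1, a contrast without the controls, BKC gave 484 genes higher and 226 lower, 301 in all with the 2 groups alone. With the clock score as a covariate it gave 265 (median absolute log2 fold change 0.63, from 0.69). Saa3 was among the 3 largest increases (log2 fold change 3.89 ± 0.79, adjusted p = 0.00316), and Esrrb, an orphan nuclear receptor gene (-2.32 ± 0.51), and Serpinb10 (-2.17 ± 0.47) among the 3 largest decreases. In 3 lists the call held with the estimated correlation. Among 21 cholesterol synthesis genes, 15 rose, with Fdps (1.04 ± 0.18), Cyp51 (1.06 ± 0.19) and Hmgcs1 (0.91 ± 0.18) (17 over the list alone, adjusted p = 1.09e-20, or 0.0126 estimated). Of 22 chemokines and inflammatory cytokines, 4 rose, with Ccl2 (3.71 ± 0.54) (10 over the list alone, adjusted p = 9.05e-07, or 0.0460 estimated). Of 13 unfolded protein and integrated stress genes, 3 rose, with Hspa5 (1.12 ± 0.16) (5 over the list alone, adjusted p = 0.000122, or 0.0291 estimated). Of 19 lists called, 12 stayed so in every leave-one-out fit. The count was 234 and 210 without BKC 0.25 replicate 3 or 4 and 131 and 215 without BKC 1 replicate 2 or 4 in turn.

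ADEB18 at 0.5 raised 455 genes and lowered 374. Spp1 had the largest increase (log2 fold change 6.03 ± 1.19, adjusted p = 0.00264), followed by Il24 (5.47 ± 1.24), Ccl12 (log2 fold change 4.76 ± 0.72, adjusted p = 0.000343), Saa3 (4.67 ± 0.84), Ccl2 (log2 fold change 3.73 ± 0.55, adjusted p = 0.000305) and Lcn2 (3.70 ± 0.88), with Ccl7 (2.80 ± 0.58) also among the 10. Decreases included Serpinb10 (log2 fold change -2.61 ± 0.46, adjusted p = 0.000779), Zbtb16 (-2.41 ± 0.44), Adra2b (-2.28 ± 0.50), Abcd2, a peroxisomal transporter gene (-1.75 ± 0.30), and Spon2 (-1.74 ± 0.31). These 12 of 20 genes named by size kept the call in every leave-one-out fit. Of 21 cholesterol synthesis genes, 10 rose, with Cyp51 (1.01 ± 0.20) and Lss (1.44 ± 0.32) (16 over the list alone, adjusted p = 2.12e-10, or 0.168 estimated). Of 22 cell cycle genes, 5 rose, with Pcna (1.08 ± 0.24) and Cdk1 (1.29 ± 0.29) (16 over the list alone, adjusted p = 3.77e-12, or 0.168 estimated). Of 14 recruited monocyte and macrophage markers, 5 rose, with Arg1 (2.55 ± 0.46) (9 over the list alone, adjusted p = 1.94e-08, or 0.168 estimated). Of 22 chemokines and inflammatory cytokines, 3 rose (4 up and 1 down over the list alone, adjusted p = 0.00100, or 0.205 estimated). Of 15 oxidative stress (Nrf2) genes, 2 rose and 1 fell (6 up and 1 down over the list alone, adjusted p = 0.00118, or 0.168 estimated). Of 10 lists called, 9 stayed so in every leave-one-out fit. The count was 435 and 293 without Control replicate 2 or 4 in turn and 367, 434 and 461 without ADEB18 0.5 replicate 2, 3 or 4 in turn.

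Mast cell, epithelial and endothelial marker lists tested lower with ADEB18 at 0.5, with 0 or 1 member called by edgeR in each. Of 9 mast cell markers, 1 fell, the carboxypeptidase gene Cpa3 (-1.76 ± 0.52) (2 over the list alone, adjusted p = 0.000949, or 0.186 estimated). Of 11 alveolar type 1 cell markers, 1 fell, Ager (3 over the list alone, adjusted p = 0.0119, or 0.616 estimated). Of 10 club cell markers, 1 fell, Cyp4b1 (4 over the list alone, adjusted p = 0.000533, or 0.238 estimated). Endothelial markers had 0 of 15 called by edgeR and 8 lower over the list alone (adjusted p = 3.19e-06, or 0.255 estimated). The score of a set of genes that varied together across libraries, defined from these data and weighed in the closing section, stood at 5.21 ± 0.176 here, 5.11 ± 0.388 with BKC at 1 and 4.50 ± 0.116 in Control. With that score as a covariate, 158 genes were called for ADEB18 at 0.5. The call for alveolar type 1 cell markers ended without ADEB18 0.5 replicate 2 or 4 or Control replicate 2 or 4 (adjusted p up to 0.104). Cpa3 lost its call without ADEB18 0.5 replicate 1, 2, 3 or 4 or Control replicate 1, 2 or 4 (adjusted p up to 0.132). Ager lost its call without Control replicate 4 (adjusted p = 0.0638). Cyp4b1 lost its call without ADEB18 0.5 replicate 2 or Control replicate 2 or 4 (adjusted p up to 0.0649).

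**Figure D2:**
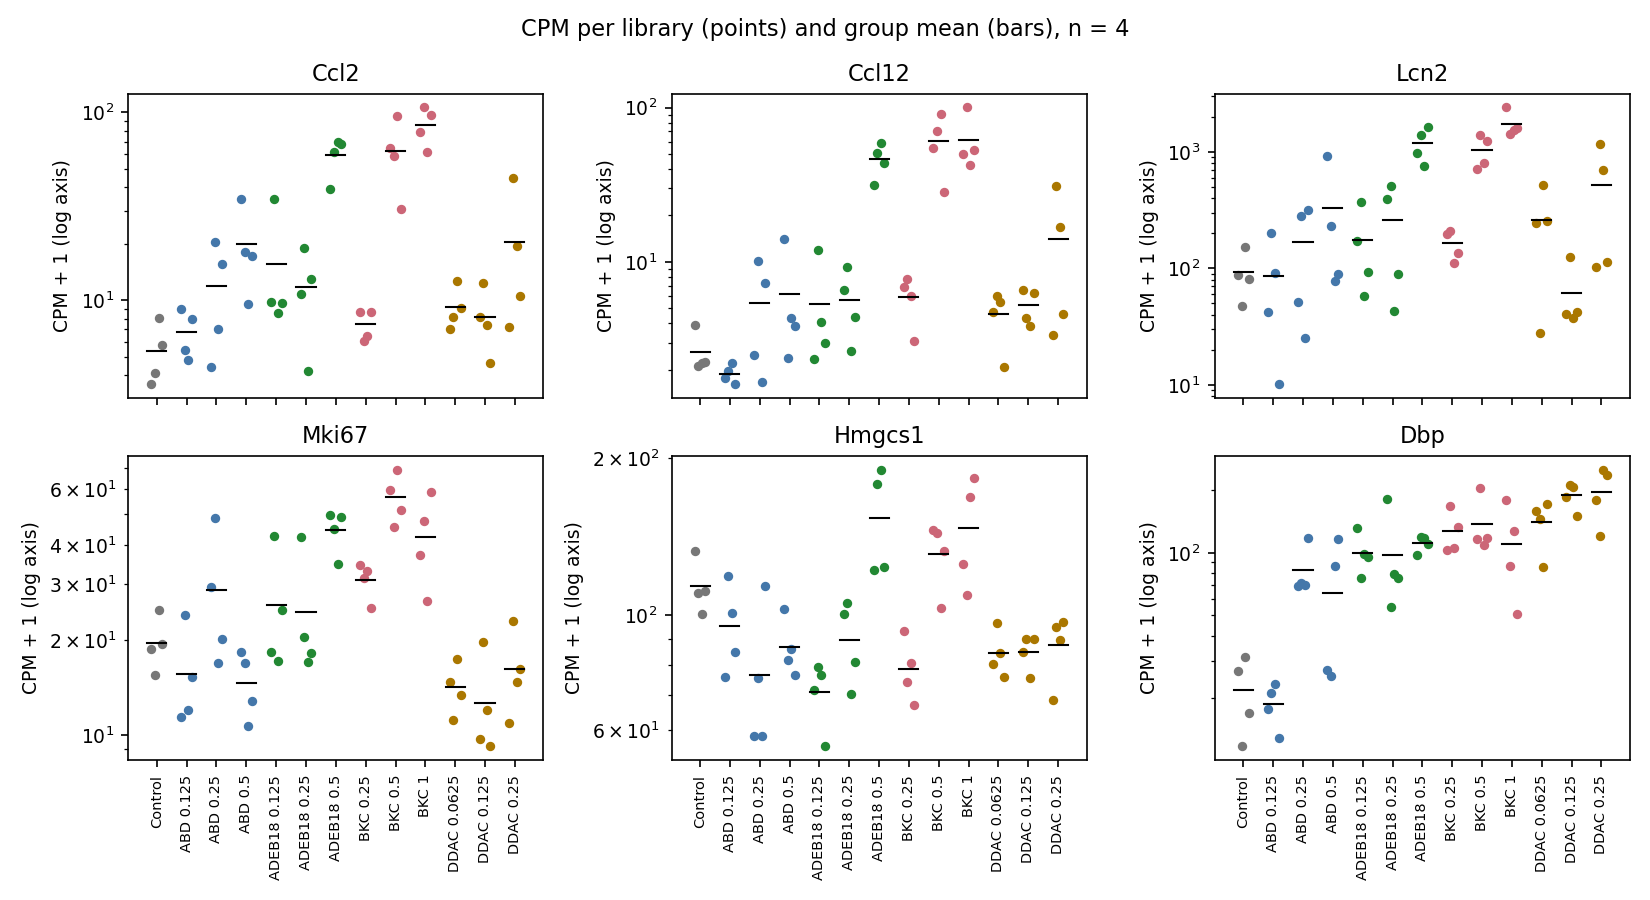
CPM plus 1 on a log axis for 6 genes in each library (points, coloured by compound) with the group mean (bar), n = 4 per group. Ccl2 averaged 4.38 CPM in Control, 58.6 with ADEB18 at 0.5 and 85.1 with BKC at 1, and Dbp averaged 20.8 CPM in Control and 196 with DDAC at 0.25.

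At its lower doses ADEB18 raised 5 genes and lowered 2. At 0.25, the clock genes Dbp (log2 fold change 2.21 ± 0.39, adjusted p = 0.00315), Nr1d1 (1.76 ± 0.33), Per3 (1.76 ± 0.30), Nr1d2 (1.10 ± 0.16) and Tef (0.81 ± 0.17) rose, and Zbtb16 (-2.65 ± 0.45) and Cd34, which codes for a surface protein of vascular and progenitor cells (-0.53 ± 0.11), fell. At 0.125, Dbp (log2 fold change 2.25 ± 0.39, adjusted p = 0.00316), Nr1d1 (1.60 ± 0.32), Per3 (1.59 ± 0.30), Nr1d2 (1.16 ± 0.16) and COX1, a mitochondrially encoded cytochrome c oxidase subunit named here after its value was seen (1.39 ± 0.21), rose. The glucocorticoid-induced gene Tsc22d3 (-0.96 ± 0.20) and Rbsn, an endosomal protein gene (-0.77 ± 0.14), fell. At 0.125, of 9 lists called, 2 stayed so in every leave-one-out fit, the clock list and, lower, cholesterol synthesis genes (0 of 21, 1 over the list alone, adjusted p = 2.30e-05, or 0.556 estimated). At 0.25, of 4 lists called, 1 stayed so in every leave-one-out fit, the clock list. At 0.125 the count was 17, 16 and 4 without Control replicate 1, 3 or 4 in turn and 4 and 17 without ADEB18 0.125 replicate 1 or 4 in turn. At 0.25 it was 2 and 2 without Control replicate 2 or 4 in turn. At 0.125, Nr1d1 lost its call without ADEB18 0.125 replicate 1 or 4 or Control replicate 1, 2 or 4 (adjusted p up to 0.140). At 0.125, Per3 lost its call without ADEB18 0.125 replicate 1 or Control replicate 1 or 2 (adjusted p up to 0.174). At 0.125, Tsc22d3 lost its call without ADEB18 0.125 replicate 1, 2, 3 or 4 or Control replicate 4 (adjusted p up to 0.353). At 0.125, Rbsn lost its call without ADEB18 0.125 replicate 3 or Control replicate 4 (adjusted p up to 0.145). At 0.25, Dbp lost its call without ADEB18 0.25 replicate 1 or Control replicate 2 or 4 (adjusted p up to 0.0993). At 0.25, Nr1d1 lost its call without Control replicate 1, 2 or 4 (adjusted p up to 0.108). At 0.25, Per3 lost its call without Control replicate 2 (adjusted p = 0.0690). At 0.25, Zbtb16 lost its call without Control replicate 4 (adjusted p = 0.0890). At 0.25, Cd34 lost its call without ADEB18 0.25 replicate 1, 2, 3 or 4 or Control replicate 2, 3 or 4 (adjusted p up to 0.193).

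From 0.125 to 0.5, ADEB18 gave 303 genes higher and 132 lower, 229 and 177 with DESeq2 size factors and 366 and 351 by DESeq2. With the set score as a covariate it gave 203 (median absolute log2 fold change 0.57, from 0.65). The cholesterol list held its call with the estimated correlation. Of 21 genes, 13 rose, with Cyp51 (1.43 ± 0.20), Hmgcs1 (1.13 ± 0.18) and Fdps (1.04 ± 0.18) (17 over the list alone, adjusted p = 2.09e-27, or 0.00248 estimated). The largest increase was of Ccl12 (log2 fold change 3.36 ± 0.66, adjusted p = 0.00318), and Abcd2 (log2 fold change -1.73 ± 0.30, adjusted p = 0.000578) was among the 3 largest decreases. Of 10 lists called, 5 stayed so in every leave-one-out fit, which were also chemokines and inflammatory cytokines (3 of 22 up, adjusted p = 0.000238, or 0.255 estimated), recruited monocyte and macrophage markers, alveolar type 2 cell markers and cell cycle genes (estimated adjusted p = 0.432, 0.255 and 0.566). The count was 239 and 176 without ADEB18 0.125 replicate 1 or 3 in turn and 267, 192, 158 and 230 without ADEB18 0.5 replicate 1, 2, 3 or 4 in turn.

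DDAC at 0.25 raised 277 genes and lowered 162. Clock genes led by adjusted p: Nr1d2 (log2 fold change 1.55 ± 0.16, adjusted p = 3.02e-08) and Dbp (log2 fold change 3.23 ± 0.40, adjusted p = 1.83e-06) rose, while Npas2 (log2 fold change -1.83 ± 0.32, adjusted p = 0.000985) and Bmal1 (log2 fold change -1.72 ± 0.34, adjusted p = 0.00458), which drive the clock's positive arm, fell. Ikzf4, a transcription factor gene of the Ikaros family, fell by 1.54 ± 0.27. The largest fitted increase was of Crtc2, which codes for a coactivator of CREB (log2 fold change 5.23 ± 1.27, adjusted p = 0.0207), and Ccl12 (log2 fold change 2.97 ± 0.70, adjusted p = 0.0175) and Ccl2 (log2 fold change 2.15 ± 0.53, adjusted p = 0.0213) rose. Dbp, Npas2, Bmal1 and Ikzf4 were the 4 of 20 genes named by size that kept the call in every leave-one-out fit. Of the 277 genes that rose, 106 belonged to the set that varied together across libraries, whose score was 5.46 ± 0.155 with DDAC at 0.25 and 4.50 ± 0.116 in Control. With that score as a covariate 14 genes were called and Crtc2 turned to -0.45, and with the clock score 2 were called. Crtc2 belongs to that set, so a smaller fold with the set score is partly built in. Every DDAC library had a higher clock score than every Control library. A clock effect and a response to DDAC therefore cannot be told apart by the clock covariate. The count was 249, 285, 254 and 95 without Control replicate 1, 2, 3 or 4 in turn and 272, 84 and 137 without DDAC 0.25 replicate 1, 2 or 3 in turn. Crtc2 lost its call without Control replicate 1, 3 or 4 or DDAC replicate 2 (adjusted p up to 0.0834). Ccl12 did without Control replicate 4 or DDAC replicate 2 (adjusted p up to 0.127). Ccl2 did without Control replicate 1, 2 or 4 or DDAC replicate 2 (adjusted p up to 0.20).

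Cardiac muscle genes were low in libraries of DDAC at 0.25, with a list score of 1.33 ± 1.26 against 5.24 ± 3.28 in Control. In that list 0 of 10 members were called by edgeR and 10 were lower over the list alone (adjusted p = 1.68e-05, or 0.840 estimated). Goblet and mucous genes had 0 of 11 called and 3 lower over the list alone (adjusted p = 0.0126, or 0.880 estimated), with a score of 1.87 ± 0.963 against 3.66 ± 1.43. Of 6 lists called, 3 stayed so in every leave-one-out fit. Of 12 immediate early genes, 2 rose, the nuclear receptor gene Nr4a1 and the RNA-binding protein gene Zfp36 (4 over the list alone, adjusted p = 0.000703, or 0.840 estimated). The call for goblet and mucous genes ended without Control replicate 3 or DDAC 0.25 replicate 4 (adjusted p up to 0.170). Nr4a1 and Zfp36 lost their calls when any 1 library of either group was left out (adjusted p up to 0.118 and 0.121).

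DDAC at 0.125 raised 104 genes and lowered 159, and at 0.0625 it raised 165 and lowered 247. With the 2 groups alone in the fit the balance turned, to 157 up and 49 down at 0.125 and 222 up and 90 down at 0.0625. Bmal1 was among the 3 largest decreases at 0.125 (log2 fold change -1.67 ± 0.34, adjusted p = 0.00779), and Cyp26b1, whose product breaks down retinoic acid, at 0.0625 (log2 fold change -2.07 ± 0.38, adjusted p = 0.00143). Of the genes that rose, 37 of the 104 and 54 of the 165 belonged to the set that varied together, whose scores were 5.33 ± 0.159 and 5.32 ± 0.0711. With that score as a covariate edgeR called 8 and 50 genes, and with the clock score 0 and 2. At 0.0625, of 4 lists called, 2 stayed so in every leave-one-out fit. At 0.125, 1 of 12 immediate early genes rose (2 over the list alone, adjusted p = 0.00128, or 0.915 estimated). At 0.0625, 1 of 12 immediate early genes rose (3 over the list alone, adjusted p = 0.00105, or 0.878 estimated), and 1 of 10 B and plasma cell markers rose, the receptor gene Cd79b (4 over the list alone, adjusted p = 0.00496, or 0.878 estimated). At 0.125 the count was 143 and 85 without Control replicate 3 or 4 in turn and 51, 121 and 91 without DDAC 0.125 replicate 1, 2 or 3 in turn. At 0.0625 it was 252 and 137 without Control replicate 2 or 4 in turn and 193, 264 and 158 without DDAC 0.0625 replicate 1, 2 or 3 in turn. At 0.0625, the call for B and plasma cell markers ended without Control replicate 2 (adjusted p = 0.0778). Cd79b lost its call without Control replicate 2 or DDAC 0.0625 replicate 2 or 3 (adjusted p up to 0.0887).

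Between 0.0625 and 0.25, edgeR called 2 genes higher and 2 lower with DDAC, and DESeq2 17 in all. Zbtb16 (log2 fold change 3.10 ± 0.45, adjusted p = 0.000135) and Fhip1b (0.62 ± 0.13) were higher at 0.25, and COX1 (log2 fold change -1.48 ± 0.22, adjusted p = 0.000135) and Creb3l1, a transcription factor gene (-0.95 ± 0.18), lower. Zbtb16 ran from 39.7 ± 8.34 CPM to 341 ± 79.4 CPM, with 182 ± 144 CPM in Control. Of 10 lists called, 4 stayed so in every leave-one-out fit: T cell markers, B and plasma cell markers, goblet and mucous genes (estimated adjusted p = 0.138, 0.138 and 0.536) and cardiac muscle genes, all lower at 0.25, of which the cardiac list had 10 of 10 lower over the list alone (adjusted p = 1.16e-06, or 0.441 estimated). The count was 2 and 2 without DDAC 0.25 replicate 3 or 4 in turn. Fhip1b lost its call when any 1 library of either group was left out (adjusted p up to 0.305). Creb3l1 lost its call without DDAC 0.0625 replicate 3 or DDAC 0.25 replicate 3 or 4 (adjusted p up to 0.188).

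**Figure D3:**
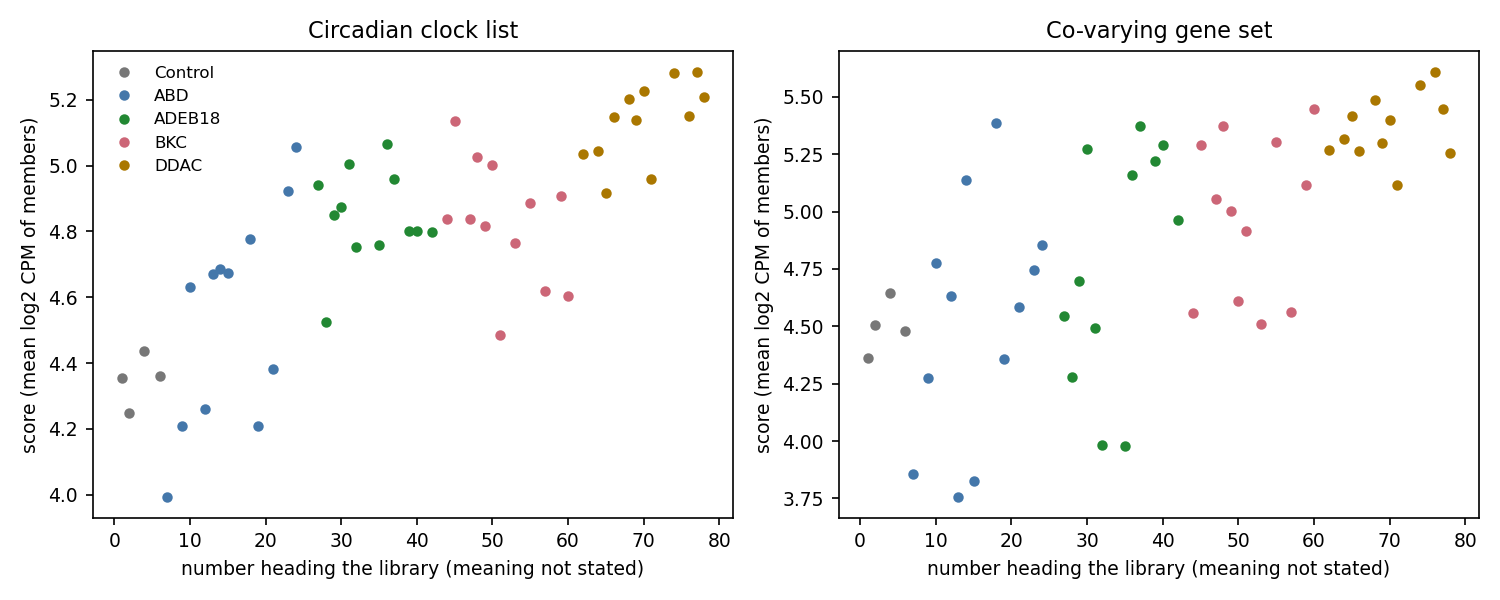
Score of each library (mean log2 CPM of the members) for the circadian clock list (left) and the set of 363 genes that varied together (right), against the number that heads the library, whose meaning is not stated. The mean clock score was 4.35 in Control and 5.23 with DDAC at 0.25.

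With ABD edgeR called few genes. At 0.5, 3 rose: the clock genes Nr1d2 (log2 fold change 0.99 ± 0.16, adjusted p = 0.00288) and Per3 (1.61 ± 0.30), and the sodium and proton exchanger gene Slc9a5, named here after its value was seen (1.97 ± 0.37). At 0.25, 4 rose: Nr1d2 (log2 fold change 1.02 ± 0.16, adjusted p = 0.00161), Dbp (1.96 ± 0.38), Per3 (1.57 ± 0.30) and the histone gene H2bc18 (1.38 ± 0.27). At 0.125, edgeR called 0 genes, with 728 at an unadjusted p under 0.05 and 2 called by DESeq2. Ccl2 stood at 18.9 ± 10.5 CPM at 0.5 and did not pass (log2 fold change 2.10 ± 0.53, adjusted p = 0.239). At 0.5, of 10 lists called, 5 stayed so in every leave-one-out fit: the clock list, immediate early genes (0 of 12, 2 over the list alone, adjusted p = 0.000848, or 0.818 estimated) higher, and ciliated cell markers, club cell markers and goblet and mucous genes lower, each with 0 members called by edgeR and estimated adjusted p = 0.818. The goblet and ciliated scores followed the cardiac score within groups, as given in the closing section. With ABD at 0.5 the cardiac score was 4.25 ± 3.47 against 5.24 ± 3.28 in Control, and the goblet score 1.90 ± 1.25 against 3.66 ± 1.43. At 0.25 the clock list was the 1 of 7 that did so, and at 0.125 0 of 2 did. At 0.5 the count was 0 and 1 without Control replicate 1 or 3 in turn and 6, 5, 1 and 0 without ABD 0.5 replicate 1, 2, 3 or 4 in turn. At 0.25 it was 1 and 2 without Control replicate 2 or 4 in turn and 1 and 7 without ABD 0.25 replicate 1 or 3 in turn. At 0.5, Nr1d2 lost its call without ABD replicate 4 or Control replicate 1 (adjusted p up to 0.0959). Per3 did without ABD replicate 3 or 4 or Control replicate 1, 2 or 3 (adjusted p up to 0.363). At 0.25, Dbp lost its call without ABD replicate 1 or 4 or Control replicate 1, 2 or 4 (adjusted p up to 0.276). Per3 did without ABD replicate 1 or Control replicate 1, 2 or 3 (adjusted p up to 0.186). H2bc18 did without ABD replicate 1 or 3 or Control replicate 2, 3 or 4 (adjusted p up to 0.243).

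From 0.125 to 0.5, edgeR called 3 genes higher with ABD and 0 lower, with 1078 at an unadjusted p under 0.05 and 8 called by DESeq2. These were the clock genes Nr1d1 (log2 fold change 1.94 ± 0.33, adjusted p = 0.00415) and Nr1d2 (log2 fold change 1.10 ± 0.16, adjusted p = 0.000290), and Slc9a5 (1.89 ± 0.37). Of 10 lists called, 2 stayed so in every leave-one-out fit, the clock list and, higher, chemokines and inflammatory cytokines (0 of 22, 3 over the list alone, adjusted p = 2.87e-05, or 0.172 estimated). The count was 1 and 1 without ABD 0.125 replicate 1 or 4 in turn and 6 and 1 without ABD 0.5 replicate 1 or 4 in turn. Nr1d1 lost its call without ABD 0.125 replicate 1 or 4 or ABD 0.5 replicate 4 (adjusted p up to 0.132).

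The list test called circadian clock genes in 11 of the 12 comparisons with Control, and in 6 with the estimated correlation. The list holds 12 tested members, among them the output gene Dbp, the repressors Nr1d1 and Nr1d2 and the positive-arm genes Bmal1 and Npas2, which peak at other times of day. Numbers over the list alone, marked alone, are given as up, then down. With ABD, calls at 0.25 were 3 up, 5 and 2 alone, adjusted p = 0.000197, or 0.111 estimated. At 0.5 they were 2 up, 6 and 0 alone, adjusted p = 0.000848, or 0.289 estimated. At 0.125 ABD had 0 called by edgeR or over the list alone (adjusted p = 0.623, or 0.942 estimated). With ADEB18, calls at 0.125 were 4 up, 6 and 1 alone, adjusted p = 2.30e-05, or 0.0457 estimated. At 0.25 they were 5 up, 6 and 1 alone, adjusted p = 1.06e-08, or 0.00215 estimated. At 0.5 they were 6 up, 6 and 2 alone, adjusted p = 0.000949, or 0.168 estimated. With BKC, calls at 0.25 were 5 up, 6 and 3 alone, adjusted p = 1.65e-07, or 0.00612 estimated. At 0.5 they were 6 up and 2 down, 6 and 2 alone, adjusted p = 0.00730, or 0.189 estimated. At 1 they were 6 up and 1 down, 6 and 2 alone, adjusted p = 0.0119, or 0.186 estimated. With DDAC, calls at 0.0625 were 5 up, 6 and 3 alone, adjusted p = 2.88e-06, or 0.0167 estimated. At 0.125 they were 6 up and 2 down, 6 and 3 alone, adjusted p = 9.91e-10, or 0.00105 estimated. At 0.25 they were 6 up and 2 down, 7 and 2 alone, adjusted p = 7.65e-11, or 0.000450 estimated. Between the doses of ABD they were 2 up, 6 and 0 alone, adjusted p = 2.87e-05, or 0.0482 estimated. The list score was 4.35 ± 0.0784 in Control, 4.75 ± 0.166 with BKC at 1 and 5.23 ± 0.0645 with DDAC at 0.25.

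**Figure D4:**
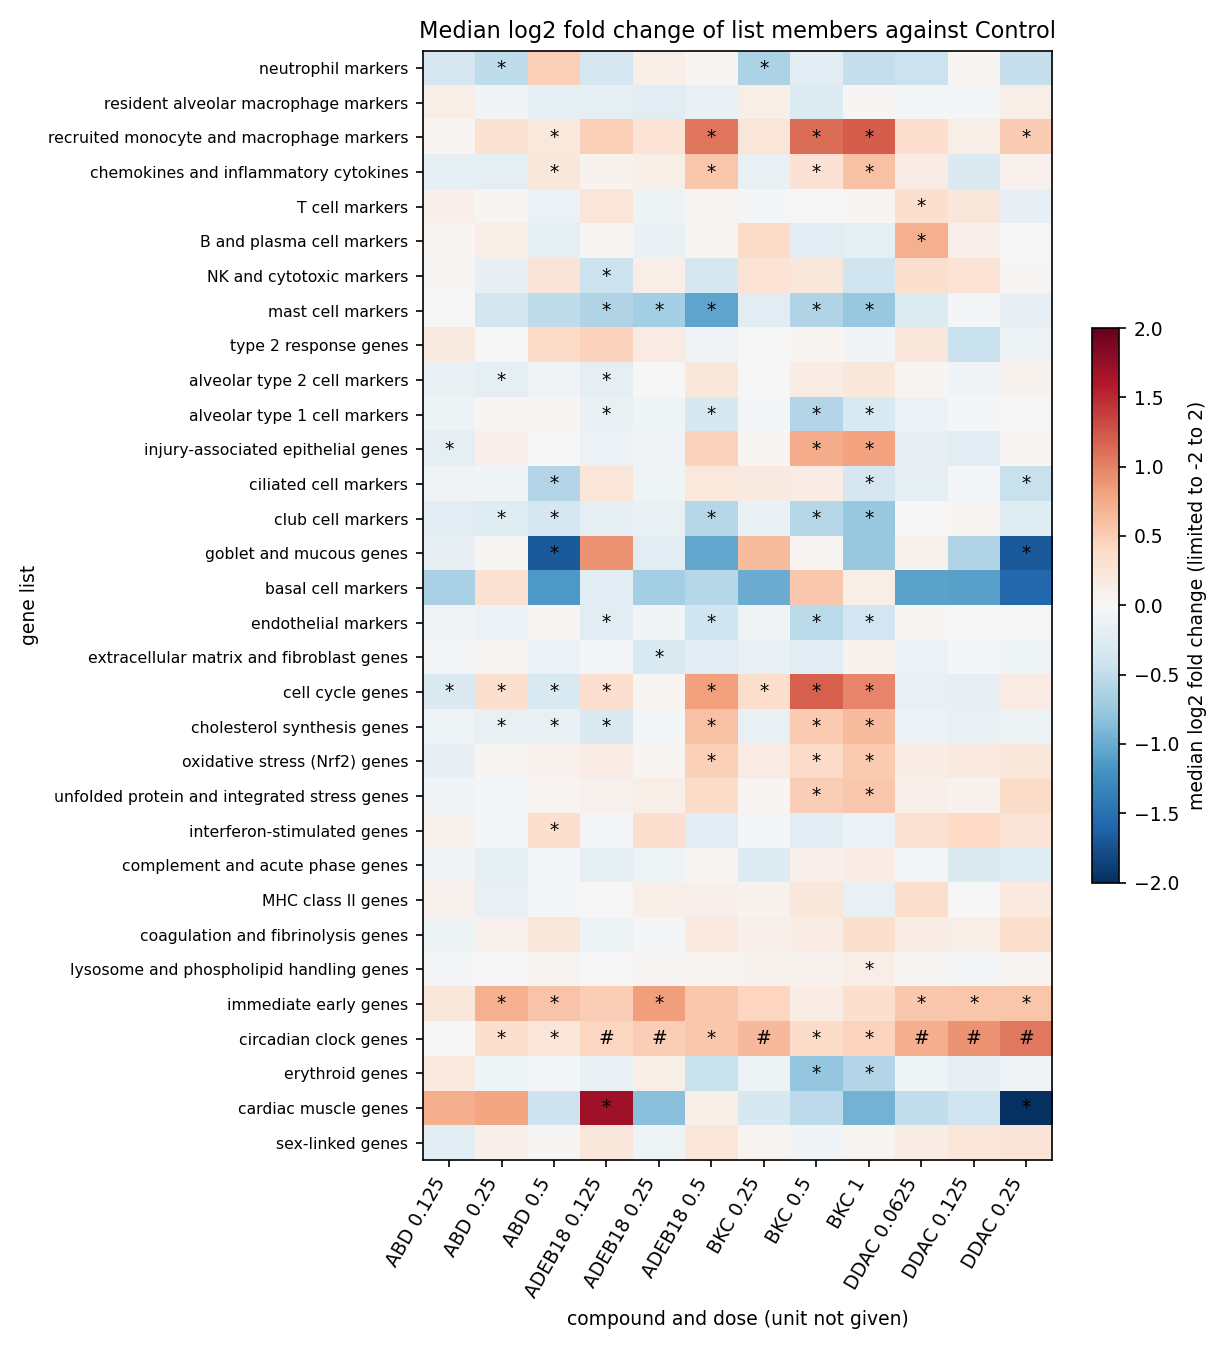
Median log2 fold change of the members of each of the 32 lists against Control, with colour limited to -2 to 2, for the 12 dosed groups. A # marks a list called with the preset and the estimated correlation and a * a list called with the preset one alone, and the # marks stand in 6 cells, all in the clock list.

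Direct contrasts between compounds at the same dose value ask where the compounds differ. At 0.5, BKC against ABD gave 785 genes higher and 689 lower (914 in all with the 2 groups alone). Ccl12 (log2 fold change 3.53 ± 0.66, adjusted p = 0.000849) and Fam25a were among the 3 largest increases and Rasl11a (adjusted p = 0.00196) among the 3 largest decreases. Of 22 cell cycle genes, 19 were higher, with Cdk1 (1.96 ± 0.30) and Mki67 (2.03 ± 0.33) (22 over the list alone, adjusted p = 7.03e-26, or 0.0504 estimated). Of 21 cholesterol synthesis genes, 14 were higher, with Cyp51 (1.21 ± 0.20) (15 over the list alone, adjusted p = 8.33e-13, or 0.0759 estimated). Of 15 endothelial markers, 9 were lower, with Cldn5 (-0.92 ± 0.17) (11 over the list alone, adjusted p = 2.96e-10, or 0.209 estimated). Of 14 recruited monocyte and macrophage markers, 4 were higher (9 over the list alone, adjusted p = 6.73e-06, or 0.373 estimated). Of 11 lists called, 6 stayed so in every leave-one-out fit. The count was 741 and 846 without ABD 0.5 replicate 3 or 4 in turn and 412 without BKC 0.5 replicate 3.

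ADEB18 against ABD at 0.5 gave 335 genes higher and 289 lower, 1437 in all with the 2 groups alone. With the set score (5.21 ± 0.176 against 4.64 ± 0.216) as a covariate it gave 105 (median absolute log2 fold change 0.59, from 0.68). Ccl12 (log2 fold change 3.12 ± 0.65, adjusted p = 0.00695) was the largest increase, and Esrrb (-2.36 ± 0.51), Serpinb10 (-2.08 ± 0.45) and Abcd2 (log2 fold change -1.85 ± 0.30, adjusted p = 0.00106) the largest decreases. The cholesterol list held its call with the estimated correlation. Of 21 genes, 11 were higher, with Cyp51 (1.36 ± 0.20) (18 over the list alone, adjusted p = 2.83e-18, or 0.0303 estimated). Of 22 cell cycle genes, 15 were higher (20 over the list alone, adjusted p = 8.48e-20, or 0.0778 estimated). Of 15 endothelial markers, 4 were lower (7 over the list alone, adjusted p = 7.61e-07, or 0.452 estimated). Of 9 lists called, 7 stayed so in every leave-one-out fit. The count was 318, 180 and 269 without ABD replicate 2, 3 or 4 and 353, 234, 239 and 288 without ADEB18 replicate 1, 2, 3 or 4 in turn.

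BKC against ADEB18 at 0.5 gave 0 genes by edgeR, with 687 at an unadjusted p under 0.05 and 2 called by DESeq2. The log2 difference with its 95% interval was 0.07 (-0.89 to 1.02) for Ccl2, 0.33 (-1.51 to 2.17) for Spp1, 0.35 (-0.28 to 0.97) for Mki67, -0.15 (-0.54 to 0.24) for Cyp51 and -0.21 (-0.55 to 0.14) for Cldn5, genes chosen after their values were seen. For 61.0% of the genes tested that interval lay within 2-fold. Of 6 lists called, 0 stayed so in every leave-one-out fit.

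At 0.25, Zbtb16, which codes for a zinc finger transcription factor, was higher with DDAC than with each other compound: log2 fold change 2.54 ± 0.44, adjusted p = 0.00419 against ABD, 3.56 ± 0.46 against ADEB18 and 3.42 ± 0.46 against BKC. DDAC against ABD gave 154 genes higher and 75 lower (272 and 264 by DESeq2), with the transcription factor gene Klf15 (1.83 ± 0.36) among the 3 largest increases, and DDAC against ADEB18 gave 166 higher and 67 lower. Of the genes higher, 33 of 154 and 80 of 166 belonged to the set that varied together, whose score was 5.46 ± 0.155 with DDAC, 4.53 ± 0.855 with ABD and 4.40 ± 0.560 with ADEB18. With that score as a covariate edgeR called 0 and 1 genes, with the clock score 1 and 6, and with the 2 groups alone 2 and 104. Against ABD, of 2 lists called, 2 stayed so in every leave-one-out fit: circadian clock genes (2 of 12, 7 over the list alone, adjusted p = 0.000935, or 0.221 estimated) higher and cardiac muscle genes (0 of 10, 10 over the list alone, adjusted p = 1.29e-05, or 0.890 estimated) lower. Against ADEB18, of 5 lists called, 1 stayed so in every leave-one-out fit, cardiac muscle genes (0 of 10, adjusted p = 0.00283, or 0.937 estimated) lower. The cardiac score was 1.33 ± 1.26 with DDAC, 5.38 ± 3.78 with ABD, 3.87 ± 3.16 with ADEB18 and 6.01 ± 0.968 with BKC at 0.25. Against ABD the count was 8, 14 and 938 without ABD 0.25 replicate 1, 3 or 4 in turn and 41, 33, 104 and 122 without DDAC 0.25 replicate 1, 2, 3 or 4 in turn. Against ADEB18 it was 48, 54, 4 and 587 without ADEB18 0.25 replicate 1, 2, 3 or 4 in turn and 44, 23 and 77 without DDAC 0.25 replicate 1, 2 or 3 in turn. Against ABD, Klf15 lost its call without ABD 0.25 replicate 1 or 3 (adjusted p up to 0.0979).

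DDAC against BKC at 0.25 gave Zbtb16 higher and 5 genes lower: the nucleolar protein gene Gnl3l (log2 fold change -1.26 ± 0.22, adjusted p = 0.00623), the transcription coactivator gene Mrtfb (adjusted p = 0.0372) and Palm2 (-1.28 ± 0.26), and, named after their values were seen, the kinase gene Stk4 (-0.58 ± 0.12) and Trip11, a Golgi protein gene (-0.53 ± 0.11). DESeq2 called 44, and edgeR 105 with the 2 groups alone. For 59.6% of genes the 95% interval of the difference lay within 2-fold, and the difference was 1.59 (0.57 to 2.62) for Ccl2 and 0.64 (-0.09 to 1.37) for Dbp. Of 5 lists called, 3 stayed so in every leave-one-out fit: ciliated cell markers, goblet and mucous genes (estimated adjusted p = 0.718 and 0.393) and cardiac muscle genes, all lower, with 9 of 10 of the last lower over the list alone (adjusted p = 6.21e-11, or 0.393 estimated). The count was 1, 2 and 3 without BKC 0.25 replicate 1, 3 or 4 in turn and 3, 2, 2 and 1 without DDAC 0.25 replicate 1, 2, 3 or 4 in turn. Gnl3l lost its call without BKC replicate 1 or DDAC replicate 4 (adjusted p up to 0.0545). Mrtfb did without BKC replicate 1, 3 or 4 or DDAC replicate 2, 3 or 4 (adjusted p up to 0.253). Palm2 did without BKC replicate 1, 3 or 4 or DDAC replicate 1, 2, 3 or 4 (adjusted p up to 0.253). Stk4 and Trip11 lost theirs at least without BKC replicate 1 or DDAC replicate 4.

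Cd34 was lower at 0.25 with BKC (log2 fold change -0.75 ± 0.11, adjusted p = 0.000117) and with ADEB18 (log2 fold change -0.76 ± 0.11, adjusted p = 0.000104) than with ABD. BKC against ABD gave 7 genes higher and 16 lower (7 in all with the 2 groups alone, 3 with the set score as a covariate and 61 with the cardiac score), with the redox regulator gene Txnip (1.36 ± 0.26) and the histone demethylase gene Kdm6a (0.78 ± 0.15) up, and no list passed. ADEB18 against ABD gave 1 gene higher, Vps72 (1.13 ± 0.22), and 2 lower, Cd34 and the DNA repair gene Mgmt (-0.78 ± 0.15), with 31 called by DESeq2, and of 3 lists called, 0 stayed so in every leave-one-out fit. BKC against ADEB18 gave 0 genes by edgeR and 0 by DESeq2, with 996 at an unadjusted p under 0.05. Its difference with the 95% interval was -0.72 (-1.75 to 0.31) for Ccl2, 0.38 (-0.35 to 1.11) for Dbp and 0.14 (-0.73 to 1.00) for Zbtb16, and the interval lay within 2-fold for 60.3% of genes. There, of 6 lists called, 1 stayed so in every leave-one-out fit, neutrophil markers (0 of 10, 1 over the list alone, adjusted p = 8.66e-05, or 0.418 estimated) lower. For BKC against ABD the count was 4, 48, 1 and 114 without ABD 0.25 replicate 1, 2, 3 or 4 in turn and 5, 1, 11 and 1 without BKC 0.25 replicate 1, 2, 3 or 4 in turn. For ADEB18 against ABD it was 5 and 1 without ABD 0.25 replicate 2 or 3 in turn and 5, 1 and 1 without ADEB18 0.25 replicate 2, 3 or 4 in turn. For BKC against ABD, Txnip lost its call without ABD replicate 1 or 3 or BKC replicate 2 or 4 (adjusted p up to 0.147). Kdm6a did without ABD replicate 3 or BKC replicate 2 or 4 (adjusted p up to 0.117). For ADEB18 against ABD, Vps72 lost its call without ABD replicate 1, 3 or 4 or ADEB18 replicate 1, 3 or 4 (adjusted p up to 0.275). Mgmt did without ABD replicate 1, 3 or 4 or ADEB18 replicate 3 or 4 (adjusted p up to 0.150).

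At 0.125, ADEB18 against ABD gave 3 genes, all clock genes and all higher: Dbp (log2 fold change 2.48 ± 0.39, adjusted p = 0.000527), Nr1d1 (log2 fold change 2.27 ± 0.33, adjusted p = 0.000158) and Nr1d2 (log2 fold change 1.27 ± 0.16, adjusted p = 8.08e-06). The clock list there had 3 up, 6 and 1 over the list alone, adjusted p = 8.70e-08, or 0.00563 estimated, and of 9 lists called, 2 stayed so in every leave-one-out fit, this one and, higher, cell cycle genes (0 of 22, 1 over the list alone, adjusted p = 3.34e-11, or 0.442 estimated). DDAC against ABD gave 187 genes higher and 163 lower (170 in all with the 2 groups alone and 0 with the clock score as a covariate), with Dbp (log2 fold change 3.40 ± 0.40, adjusted p = 3.97e-07) and Nr1d1 (3.00 ± 0.34) among the 3 largest increases and the clock list the list called: 6 up and 2 down, 6 and 3 over the list alone, adjusted p = 1.30e-10, or 0.000510 estimated. Of the 187, 72 belonged to the set that varied together, whose scores were 5.33 ± 0.159 and 4.38 ± 0.410. With that score as a covariate edgeR called 8 genes, and 1 for DDAC against ADEB18. DDAC against ADEB18 gave 84 higher and 103 lower. EdgeR called 12 with the cardiac score (2.96 ± 3.46 against 7.91 ± 1.62) as a covariate, 0 with the clock score and 0 with the 2 groups alone. There of 7 lists called, 3 stayed so in every leave-one-out fit: NK and cytotoxic markers (1 of 10, 7 over the list alone, adjusted p = 1.64e-06, or 0.298 estimated) higher, and cell cycle genes and cardiac muscle genes lower (estimated adjusted p = 0.693 and 0.724). For DDAC against ABD the count was 75 and 127 without ABD replicate 1 or 2 and 126, 202 and 137 without DDAC replicate 1, 2 or 3 in turn. For DDAC against ADEB18 it was 85, 28, 44 and 574 without ADEB18 replicate 1, 2, 3 or 4. It was 20, 3 and 117 without DDAC replicate 1, 3 or 4.

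Genes called in the same direction for more than 1 compound were counted, since all comparisons with Control share its 4 libraries. At 0.5, ADEB18 and BKC shared 335 up and 266 down (22.1 and 16.1 for independent lists), and 72.5 in all with the controls split into 2 and 2 (median of 6 ways), where no control is shared and each comparison has fewer controls, so the part of each in the fall is not known. The covariance of their log2 fold changes was 0.446 against 0.240 in simulated groups that differ from Control by sampling alone. At 0.25, BKC and DDAC shared 7 up and 14 down (0.171 and 0.237 for independent lists), 3.5 in all with the controls split, with a covariance of 0.382 against 0.245. ADEB18 shared 5 up and 0 down (0.0778 and 0.0182 for independent lists) with DDAC at 0.25 and 5 up and 2 down (0.00309 and 0.00292 for independent lists) with BKC, 1 and 0 with the controls split. ABD at 0.25 shared 3, 3 and 4 up and 0 down with ADEB18, BKC and DDAC, 0, 0 and 1 with the controls split, and had covariances near the simulated ones: 0.233 against 0.244 with ADEB18, 0.255 against 0.244 with BKC and 0.243 against 0.243 with DDAC. At 0.5, where all pairs were chosen after the data were seen, ABD shared 2 up and 0 down with ADEB18 and with BKC, 0 with the controls split, and the covariances were 0.296 against 0.241 and 0.280 against 0.242. Across the highest doses, 2 genes rose with all 4 compounds, Nr1d2 and Per3, and 0 fell, while 85 rose and 47 fell with ADEB18, BKC and DDAC, not counted with the controls split.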

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

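The 3 tests on the clock, the 3 on cardiac genes, the range of the set score, the count of splits for BKC at 1 and the division of splits by a score were chosen after the result was seen. Clock genes were higher in most dosed groups. Low values in Control alone stay open. The 3 clock genes called between ADEB18 and ABD at 0.125 cannot decide, as ABD scored low too (4.27, Control 4.35). A collection time that follows the number heading each library stays open: the clock score and that number had r = 0.760 over all libraries, and within groups r = 0.209 (permutation p = 0.221, rho = 0.123, p = 0.459, r = 0.202 without the 2 farthest libraries, adjusted p = 0.221 over 6 relations). That number runs in group order, so r over all libraries cannot tell it from compound and dose. A clock response that grows with dose stays open too, with a slope of 0.0503 per log2 dose over all compounds (permutation p = 0.176). By compound the slope was 0.184 for ABD, 0.0213 for ADEB18, -0.102 for BKC and 0.0979 for DDAC. The positive-arm genes Bmal1 and Npas2 ran against the output and repressor genes within groups (r = -0.340, p = 0.0275, rho = -0.360, p = 0.0263, r = -0.343 without 2, adjusted p = 0.0331), a relation the clock itself gives.

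Cardiac muscle genes were near 0 in 3 of the 4 libraries of DDAC at 0.25. Within groups, 10 cardiac genes outside the list followed the list score (r = 0.993, rho = 0.992, r = 0.993 without the 2 farthest libraries), as did the basal cell score (r = 0.814, rho = 0.814, 0.795 without 2) and the goblet score (r = 0.835, rho = 0.825, 0.811 without 2). Each had a permutation p = 1e-05, the smallest that 100000 permutations of the 52 libraries give, and adjusted p = 2e-05 over 6 relations. The ciliated score followed too (r = 0.606, p = 4e-05, rho = 0.606, p = 8e-05, 0.564 without 2, adjusted p = 6e-05). Cardiac-type muscle and large airway tissue in the sampled piece, in an amount that varies between rats, could give these values. Whether such muscle came from the heart or from the lung itself was not tested. A fall caused by DDAC stays open, with an exact permutation p of 0.143 for the score difference of -3.91. Marker genes of cartilage did not follow (median r = 0.0164 for 2 genes).

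Ubiquitous genes of low count, such as Crtc2 and Reck, were among the genes higher in the DDAC groups, and many belonged to the set that varied together. A library property that also varies within groups stays open. The range of the set score inside ABD at 0.25, 1.63, against a difference of 0.968 between DDAC at 0.25 and Control, says nothing, since the set was chosen for varying within such groups. Copies named as pseudogenes were known for 21.7% of the set and 9.34% of other tested genes (odds ratio 2.69, Fisher p = 7.02e-12), so reads shared with such copies could contribute. With the set score as a covariate, 50, 8 and 14 genes were called for DDAC from low to high dose. The median absolute log2 fold change of the called genes went from 0.65, 0.70 and 0.78 to 0.49, 0.50 and 0.41 while its SE went from 0.153, 0.165 and 0.194 to 0.160, 0.168 and 0.189. The calls ended because the folds shrank, and since the score differs between the groups, the set score as the source of these calls cannot be told apart from a response to DDAC. For ADEB18 at 0.5 the same covariate took 829 called genes to 158, their median absolute log2 fold change from 0.68 to 0.55 and its SE from 0.176 to 0.179.

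Each comparison was refitted over the 35 splits of its 8 libraries into 4 and 4, the real one included, so counts here come from those libraries alone, given as the real count against the highest of the other splits. In 15 comparisons 1 of 35 splits, the real one, called as many genes. That is the smallest share that 35 splits can give, with no adjustment over the 28 comparisons, so each alone is limited evidence against chance. Against Control these were ADEB18 at 0.5 (1066 against 1), BKC at 0.25 (12 against 4), BKC at 0.5 (605 against 1), BKC at 1 (851 against 4), DDAC at 0.0625 (312 against 6), DDAC at 0.125 (206 against 127) and DDAC at 0.25 (539 against 14). Between doses these were ADEB18 (285 against 8), BKC (301 against 1) and DDAC (5 against 3). Between compounds at 0.25 these were BKC against ABD (7 against 1), DDAC against ADEB18 (104 against 10) and DDAC against BKC (105 against 1). Between compounds at 0.5 these were ADEB18 against ABD (1437 against 5) and BKC against ABD (914 against 3). In 7 others 2 or more of 35 splits did, so chance is not excluded. Against Control these were ABD at 0.5 (3 of 35, 4 against 13), ADEB18 at 0.125 (3 of 35, 3 against 21) and ADEB18 at 0.25 (4 of 35, 2 against 11). Between compounds at 0.125 these were ADEB18 against ABD (5 of 35, 1 against 454) and DDAC against ABD (2 of 35, 170 against 186). Between compounds at 0.25 these were ADEB18 against ABD (4 of 35, 3 against 115) and DDAC against ABD (3 of 35, 2 against 4). In 6 comparisons the real count was 0, so 35 of 35 splits call as many whatever the samples and the test says nothing: ABD at 0.125 (highest other 148), ABD at 0.25 (highest other 63), the doses of ABD (highest other 169), DDAC against ADEB18 at 0.125 (highest other 140), BKC against ADEB18 at 0.25 (highest other 222) and BKC against ADEB18 at 0.5 (highest other 5). Splits that call more genes than the real one may point to a structure of the samples. Those with 454, 169, 148, 140, 63 and 13 calls divided the 8 libraries exactly by the cardiac score, as 1 of 35 splits does, and those with 222 and 115 calls by the set score. So did, by the cardiac score, the split with 127 calls for DDAC at 0.125. Those with 186, 21, 11, 5 and 4 calls followed none of the cardiac, set and clock scores.

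Of 417 groups of 4 libraries tested, 35 held 1 library far from the other 3, where chance gives about 1 in 20. Total counts of ADEB18 0.25 replicate 2 were 9598890. List scores far from their group were 4.78 for circadian clock genes in ABD 0.25 replicate 4, 4.96 for circadian clock genes in ADEB18 0.5 replicate 1, 8.14 for cardiac muscle genes in DDAC 0.125 replicate 2 and 4.12 for recruited monocyte and macrophage markers in ABD 0.125 replicate 2. Others were 5.55 for recruited monocyte and macrophage markers in ADEB18 0.125 replicate 2, 7.61 for club cell markers in Control replicate 4 and 6.60 for club cell markers in ADEB18 0.5 replicate 4. Levels far from their group, in CPM, are given by library. Among ABD libraries these were Dbp 118 in ABD 0.25 replicate 4, Kdm6a 20.9 in ABD 0.25 replicate 1 and Ccl12 13.1 in ABD 0.5 replicate 1. Among controls these were Nr1d2 61.9 in Control replicate 3, Tsc22d3 191 and Saa3 3.55 in Control replicate 4, Ccl12 2.92 in Control replicate 1 and Cyp26b1 215 and Kng2 7.09 in Control replicate 2. Among ADEB18 libraries these were Per3 62.4 in ADEB18 0.25 replicate 1, Il24 16.6 in ADEB18 0.5 replicate 4, Zfp36 32.4 in ADEB18 0.125 replicate 4, Saa3 70.6 in ADEB18 0.125 replicate 2 and Rnf5 13.88 in ADEB18 0.25 replicate 4. Among BKC libraries these were Kng2 72.6 and Ibsp 1.45 in BKC 1 replicate 4, Fam25a 65.9 and Mmp12 75.9 in BKC 1 replicate 2 and Orm1 1.07 and Spp1 35.5 in BKC 0.25 replicate 2. Among DDAC libraries these were Gtpbp2 12.2 in DDAC 0.25 replicate 4, Hs3st6 3.48, COX1 2549 and Emx2os 1.01 in DDAC 0.25 replicate 3, Creb3l1 43.6 in DDAC 0.0625 replicate 3, Nr3c2 14.4 in DDAC 0.125 replicate 1 and Hspa1b 141 in DDAC 0.25 replicate 1.

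Direct tests between compounds at the same dose value called the numbers of genes given here. The lowest number on leaving out 1 library follows where it is under by more than 1.5 times. At 0.125, ADEB18 gave 3 against ABD and DDAC 350 (75 without ABD replicate 1). DDAC gave 187 against ADEB18 (3 without DDAC replicate 3). At 0.25 against ABD, ADEB18 gave 3 and BKC 23, each 1 without ABD replicate 3, and DDAC 229 (8 without ABD replicate 1). DDAC gave 233 against ADEB18 (4 without ADEB18 replicate 3) and 6 against BKC (1 without BKC replicate 1). At 0.5 against ABD, ADEB18 gave 624 (180 without ABD replicate 3) and BKC 1474 (412 without BKC replicate 3). By the splits above, chance is not excluded or not tested for 5 of these, the 3 at 0.125 and those of ADEB18 and DDAC against ABD at 0.25.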

How the results depend on the processing

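Among the settings planned in advance, adding the replicate number as a block left all 28 counts of called genes within 1.5 times their value, and 5 of 198 list tests and 7 of 526 named-gene values no longer passed with it. No filter on low counts moved 3 counts past 1.5 times: 24 for BKC at 0.25 (from 37), 174 for DDAC at 0.125 (from 263) and 11 for DDAC against BKC at 0.25 (from 6). A filter of at least 5 CPM in at least 4 libraries moved 3: 59 for BKC at 0.25 (from 37), 71 for BKC against ABD at 0.25 (from 23) and 354 for DDAC against ADEB18 at 0.25 (from 233). Size factors of DESeq2 in edgeR moved 1: 49 for BKC against ABD at 0.25 (from 23). Covariates and the overlap at 0.5 were chosen after seeing the data. The cause of a change was not tested where none is named.

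Numbers below run from low to high dose against Control, and in the order ABD, ADEB18, BKC and DDAC between doses. Between compounds the order is ADEB18 against ABD, DDAC against ABD and DDAC against ADEB18 at 0.125, then ADEB18, BKC and DDAC against ABD, BKC and DDAC against ADEB18 and DDAC against BKC at 0.25, then ADEB18 against ABD, BKC against ABD and BKC against ADEB18 at 0.5. By DESeq2's Wald test more genes were called in most comparisons. Against Control the numbers were 2, 11 and 12 for ABD, 37, 14 and 1303 for ADEB18, 153, 2096 and 2301 for BKC and 749, 576 and 828 for DDAC. Between doses they were 8, 717, 1076 and 17. Between compounds they were 5, 730 and 466 at 0.125, 31, 179, 536, 0, 563 and 44 at 0.25 and 1097, 1858 and 2 at 0.5.

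With the threshold of the series description, at least 2-fold and unadjusted p under 0.05, which adjusts for no multiple testing, against Control the numbers were 261, 398 and 441 for ABD, 459, 343 and 715 for ADEB18, 416, 767 and 970 for BKC and 549, 569 and 781 for DDAC. Between doses they were 428, 548, 527 and 265. Between compounds they were 367, 663 and 599 at 0.125, 465, 425, 755, 259, 621 and 377 at 0.25 and 752, 872 and 168 at 0.5.

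With only the 2 groups compared in the fit, which leaves fewer libraries to estimate the spread, against Control the numbers were 0, 0 and 4 for ABD, 3, 2 and 1066 for ADEB18, 12, 605 and 851 for BKC and 312, 206 and 539 for DDAC. Between doses they were 0, 285, 301 and 5. Between compounds they were 1, 170 and 0 at 0.125, 3, 7, 2, 0, 104 and 105 at 0.25 and 1437, 914 and 0 at 0.5.

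Leaving out each library of either group in turn, called genes ranged as follows. Against Control the numbers were 0 to 0, 1 to 7 and 0 to 6 for ABD, 4 to 17, 2 to 8 and 293 to 831 for ADEB18, 7 to 38, 467 to 2114 and 1090 to 1867 for BKC and 137 to 417, 51 to 230 and 84 to 359 for DDAC. Between doses they were 1 to 6, 158 to 418, 131 to 953 and 2 to 5. Between compounds they were 3 to 4, 75 to 398 and 3 to 574 at 0.125, 1 to 5, 1 to 114, 8 to 938, 0 to 0, 4 to 587 and 1 to 7 at 0.25 and 180 to 610, 412 to 1757 and 0 to 0 at 0.5. This moved 123 of 224 counts past 1.5 times. Calls were lost with the direction kept by 1278 of 4208 named-gene values and 265 of 1584 list tests, and 1 more list test turned. The immediate early list for BKC against ADEB18 at 0.25 turned without ADEB18 0.25 replicate 2. Its list test gave an adjusted p of 0.000215 to 0.710 over the libraries left out, and 0.0344 with all.

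With the clock list score as a covariate, against Control the numbers were 0, 5 and 2 for ABD, 9, 0 and 689 for ADEB18, 2, 1886 and 1872 for BKC and 2, 0 and 2 for DDAC. Between doses they were 0, 505, 265 and 3. Between compounds they were 2, 0 and 0 at 0.125, 2, 2, 1, 0, 6 and 3 at 0.25 and 709, 1724 and 0 at 0.5. For DDAC at 0.25 the median absolute log2 fold change of the called genes went from 0.78 to 0.49 and its SE from 0.194 to 0.279, and for ADEB18 at 0.25 from 1.76 to 0.73 and from 0.301 to 0.259. The log2 fold change of Postn in DDAC at 0.25 against Control turned from 0.74 to -0.0284.

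With the score of the set that varied together as a covariate, against Control the numbers were 0, 6 and 3 for ABD, 7, 7 and 158 for ADEB18, 8, 1706 and 1263 for BKC and 50, 8 and 14 for DDAC. Between doses they were 2, 203, 831 and 3. Between compounds they were 3, 8 and 1 at 0.125, 7, 3, 0, 0, 1 and 4 at 0.25 and 105, 1619 and 0 at 0.5. The log2 fold change of Crtc2 turned from 4.47, 4.83 and 5.23 to -0.24, -0.22 and -0.45 with DDAC from low to high dose. With the cardiac score as a covariate, 4 counts moved past 1.5 times: 12 for DDAC against ADEB18 at 0.125 (from 187), 61 for BKC against ABD at 0.25 (from 23), 103 for DDAC against ABD at 0.25 (from 229) and 2 for DDAC against BKC at 0.25 (from 6).

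The list test with an estimated correlation called 6 lists of 85 against Control, 5 of 49 between doses and 3 of 64 between compounds. With the controls split into 2 and 2, so that no control was shared and each comparison had fewer (median of 6), the genes called for both compounds and the covariance of their log2 fold changes fell. For ABD and ADEB18 at 0.25 they were 0 (from 3) and -0.00923 (from 0.233). ABD and ADEB18 at 0.5 had 0 (from 2) and 0.0694 (from 0.296). For ABD and BKC at 0.25 they were 0 (from 3) and 0.0170 (from 0.255). ABD and BKC at 0.5 had 0 (from 2) and 0.0575 (from 0.280). For ABD and DDAC at 0.25 they were 1 (from 4) and 0.00393 (from 0.243). ADEB18 and BKC at 0.25 had 0 (from 7) and 0.0626 (from 0.317). For ADEB18 and BKC at 0.5 they were 72.5 (from 601) and 0.20 (from 0.446). ADEB18 and DDAC at 0.25 had 1 (from 5) and 0.0697 (from 0.333). For BKC and DDAC at 0.25 they were 3.5 (from 21) and 0.127 (from 0.382). The covariance of ABD and ADEB18 at 0.25 turned. Total counts of 8026080 to 13852200 set the depth.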

Other observations

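Outside the lists, the transcription factor gene Zbtb16 varied widely among controls (182 ± 144 CPM) and stood at 31.8 ± 4.81 CPM with BKC at 0.25 and 341 ± 79.4 CPM with DDAC at 0.25. COX1 averaged 1442 ± 223 CPM in Control, 5350.2 ± 779 CPM with DDAC at 0.0625 and 1922 ± 421 CPM with DDAC at 0.25. Of the 85 genes that rose with ADEB18, BKC and DDAC at their highest doses, 29 belonged to the set that varied together, and Ccl2, Ccl12, Dbp, Nr1d1, Per2 and Tef were among the 85. Adm, Spon2, Nfkbia, Tppp3 and Mme were among the 47 that fell. These genes were chosen after their values were seen.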
